A study of Danio rerio with 4 samples.

How the data were processed

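Primordial germ cells of AB zebrafish embryos at 13 hours post fertilization were sorted by flow cytometry on germline EGFP, per the labels' protocols. Total RNA was extracted with the PicoPure kit, mRNA was selected on beads and libraries were made with a directional NEXTflex kit, per the labels' protocols. There were 4 libraries, 2 with a control morpholino and 2 with a morpholino against dead end, grouped by the labelled agent. The labels do not say whether the libraries of a group came from separate clutches. The labels also do not say whether the morpholino blocks translation or splicing, so a transcript level of dnd1 would not in itself check the knockdown.

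The submitters' processing notes name cutadapt 1.10, STAR 2.5.2b, Cufflinks 2.2.1 and Cuffdiff, without the version of the last, and the builds GRCz10 and Zv9 without their roles. The positions were taken as GRCz10, because the largest position on chromosome 4, 74754136, lies past the end of that chromosome in Zv9. Positions and gene names are printed as the authors' table gives them. A Cufflinks locus can join overlapping gene models, and exon or UTR annotation was not used here. The kit keeps strand, but the strand setting of the authors' quantification is not given in the sources used here. Near-identical paralogs, such as those among the Hox, ribosomal protein and her genes, can share reads in such a quantification.

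The authors' gene table held FPKM values (fragments scaled to transcript length and to the mapped fragments of the library), 1 per group, so each combines the 2 libraries of that group, per the file headers. The authors deposited the log2 ratio of dead end over control FPKM, which matched the printed FPKM values within 1.34e-05. The test statistic deposited by the authors is a score. The p-value and q-value of each gene are the authors' own, and the smallest p-value is 5e-05, so many genes share the smallest q-value of 0.00107. All 2477 rows have q under 0.05, with a largest value of 0.0498. As the table has 1 value per group, no own test of the groups was run, no standard deviation between libraries is given, and the depth is unknown. Standard errors implied by the authors' statistic, under an assumption stated there, are used only in the closing section. The authors' q rests on 2 libraries per group, and how it models their spread is not given in the sources used here. The plan fixed before the data were examined provided for this case: genes were called by the authors' q under 0.05, with at least 1 FPKM in the higher group, which left 2431 genes and took out 46. Values listed at 0 FPKM (232 genes) can be failed estimates, so no fold is given for them.

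The authors' enrichment tables came from the PANTHER overrepresentation test (release 20160715) with a Bonferroni correction over 3142 terms, per the file headers. They give the fold enrichment as the ratio of observed to expected genes and a corrected p-value, both computed by the authors. The uploaded lists are shorter than the 1609 higher and 868 lower genes of the gene table, for a reason not given in the sources used here. The authors also deposited REVIGO tables, which group similar terms, with the log10 of the p-value. These held 127 terms for higher genes and 3 for lower genes, and all of their values matched the term tables within 0.001.

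Gene lists for germ cells, embryonic tissues, signalling pathways and cell states, 29 in all, were fixed before the data were examined. Members were matched by symbol, or by a reference table of gene names that covered 2408 of the 2477 identifiers. Each list with a called member, 28 in all, was tested with a two-sided Fisher's exact test of higher against lower genes, members against all other called genes, adjusted by Benjamini-Hochberg over the 28 lists. Because the table held only called genes, this asks whether the changes of a list lean one way, not whether its genes changed more often than others. Genes are not independent replicates, so these p-values describe these libraries. The median change of each list, as log2 of (FPKM + 1), was set against 10000 random lists of the same size matched on mean expression in 20 bins. On that scale the change of low genes is understated, while the folds printed for single genes are plain FPKM ratios.

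The genes named in the text followed a rule fixed before the data were examined: the core germ cell genes, the 8 largest rises and 8 largest falls in log2 of (FPKM + 1), and up to 3 members per list with the largest change. Rows with no gene symbol or with a clone or locus name, and RNA family names, were left out of the largest rises and falls. A gene that the rule would name is not reported here. Other genes, such as the exceptions within a list, sox32 and the genes of the closing section, were named after their values were seen.

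The list test was checked on 50 simulated tables of 2431 genes. Lists with nearly all members higher were called in 0%, 90% and 100% of draws at 10, 20 and 40 members, lists with mostly lower members in 62% and 84% at 10 and 20 members, and lists with no difference in 0.3%. Most simulated lists had no difference, which makes the adjustment stricter there than over the 28 real lists. Directions were drawn independently for each gene and the simulated lists shared no members. Real lists overlap and their genes can move together, so these rates do not carry over to them. Alternatives were a pseudocount of 0.1 or 5, no minimum or a minimum of 5 FPKM, q under 0.01, a change of at least 2-fold, lists without shared members and a term p-value under 0.001. Leaving out genes listed at 0 was added after the data were seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.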

Results

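Primordial germ cells, the embryonic precursors of eggs and sperm, were sorted from zebrafish embryos of the AB strain at 13 hours post fertilization. The embryos had been injected with a control morpholino or with a morpholino against dead end, 2 libraries for each. A morpholino is a synthetic antisense oligonucleotide that blocks the use of a chosen RNA, and Dead end is an RNA-binding protein of vertebrate germ cells. Cells were sorted on an EGFP signal specific to the germline, and their polyadenylated RNA was sequenced. The comparison asks what happens to germ cell and somatic transcripts when Dead end is reduced, as the title of the series poses it. The authors' deposited table gave 1 FPKM value per gene and group, so the spread between the 2 libraries of a group could not be computed here and the depth of each library is unknown. Changes were called by the authors' q. The table used here held 2477 genes, all with q under 0.05. Other genes, among them dnd1, the gene aimed at, and the germline gene piwil1, were not analysed here.

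Most called germ cell transcripts fell and nearly all called transcripts of muscle, nervous system and other somatic tissues rose in the sorted cells of dead end morphants. The RNA-binding regulator nanos3, needed for germ cell survival, fell 3.91-fold and the iroquois transcription factor gene irx7 of the midbrain and hindbrain rose 12.1-fold in the authors' deposited table. The paraxial mesoderm regulators msgn1 and tbx6 rose 22.9-fold and 20.9-fold in the authors' deposited table. Of the 2431 genes with at least 1 FPKM in the higher group, 1599 (65.8%) were higher and 832 (34.2%) were lower with the dead end morpholino at the authors' q, counted in the authors' deposited table. Among genes with both values above 0 there, the median change was 2.96-fold for higher genes and 3.08-fold for lower genes. At q under 0.01 the same table gave 1047 higher and 416 lower genes. Called members made up only part of each fixed list, such as 16 of 28 germ cell genes and 46 of 82 neural genes. The called share was 26 of 60 for muscle and paraxial mesoderm, 12 of 64 for epidermis and 20 of 77 for extracellular matrix. Members that were not called enter none of the counts below.

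**Figure D1:**
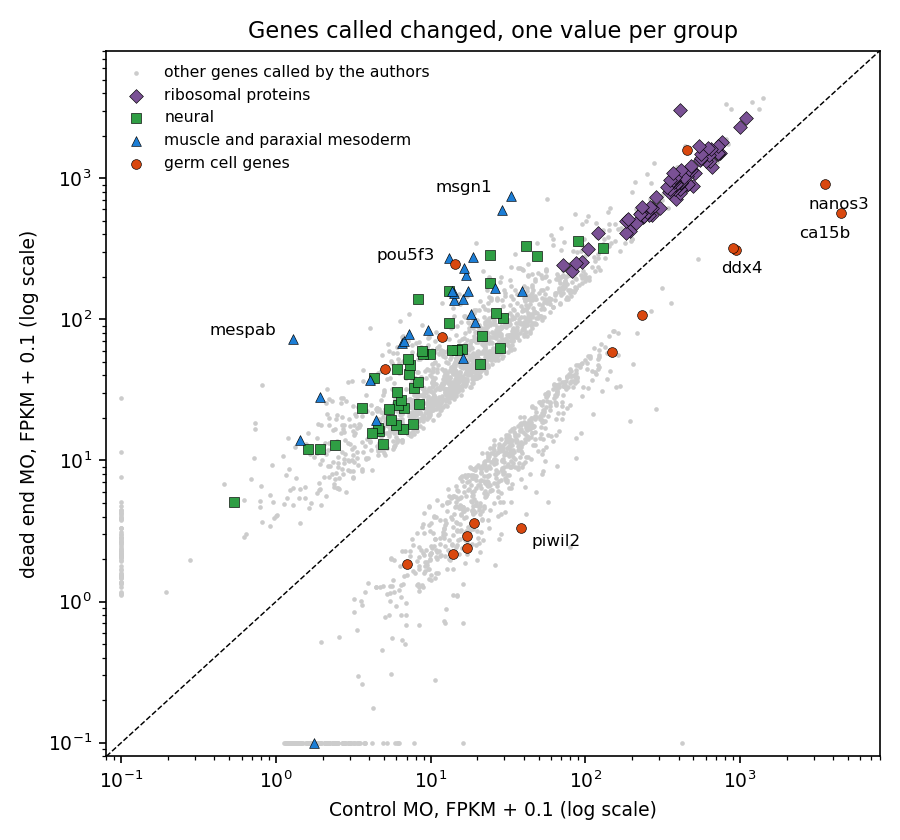
FPKM with the control morpholino (x axis) and with the dead end morpholino (y axis), both with 0.1 added and on log scales, for the 2431 genes called changed by the authors; each point is 1 gene and the dashed line marks equal values. Of the germ cell genes (orange circles), 12 lie below the line and 4 above it, while the 46 neural genes (green squares) and the 70 ribosomal protein genes (purple diamonds) all lie above it.

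Of 16 called germ cell genes, 12 were lower and 4 higher in the authors' deposited table (adjusted p = 0.00467, two-sided Fisher's exact test against all other called genes, adjusted by Benjamini-Hochberg over 28 lists). The most abundant of them in controls in the authors' deposited table, ca15b (ENSDARG00000040510, chromosome 12, 4258264 to 4264718, positions taken as GRCz10), encodes a membrane-anchored carbonic anhydrase and fell from 4484 to 568 FPKM (7.90-fold, q = 0.00107). The authors' deposited table listed nanos3 (ENSDARG00000068255, chromosome 1, 54569718 to 54570845) at 3543 FPKM in controls and 906 FPKM in dead end morphants (q = 0.00107). The germ plasm gene tdrd7a, which encodes a Tudor domain protein, fell 3.03-fold (from 941 to 310.5 FPKM, q = 0.00259) in the authors' deposited table. For ddx4 (ENSDARG00000014373, chromosome 10, 6925422 to 6946874), the vasa RNA helicase, the fall in the authors' deposited table was 2.84-fold (from 904 to 318 FPKM, q = 0.00437). The RNA-binding germ cell factor dazl fell 2.51-fold (from 148 to 58.9 FPKM, q = 0.0231) in the authors' deposited table. The 12 falls ranged from 2.17-fold to 11.8-fold with a median of 4.70-fold. The 4 members that were higher in the authors' deposited table were pou5f3 (from 14.3 to 247 FPKM), hook2 (from 4.96 to 44.4 FPKM), prdm1a (from 11.8 to 74.7 FPKM) and ybx1 (from 455 to 1590 FPKM). Of these, pou5f3 is a pluripotency factor and prdm1a also acts in somatic lineages such as slow muscle.

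Called genes of the piRNA pathway, which silences transposable elements in germ cells with small RNAs, also fell. Many of them, such as piwil2 and tdrd6, stand in the germ cell list as well, so the 2 list results overlap. Of 11 called members in the authors' deposited table, 10 were lower (adjusted p = 0.00151, Fisher's exact test). The Piwi protein gene piwil2 fell the most of these in the authors' deposited table, from 38.3 to 3.25 FPKM (11.8-fold, q = 0.00107). The Tudor domain genes tdrkh (from 17.9 to 2.44 FPKM, q = 0.00191) and tdrd6 (from 17.0 to 2.29 FPKM, q = 0.00107) fell 7.35-fold and 7.41-fold in the authors' deposited table. The exception was ddx39ab, a general RNA helicase gene of mRNA export, which was higher in the authors' deposited table (from 94.5 to 470.1 FPKM). Without members that another list also holds, 4 of 6 germ cell genes and 2 of 3 piRNA pathway genes were lower in the authors' deposited table, and neither split passed Fisher's exact test (adjusted p = 0.354 and 0.428). The meiosis list had no called member here and was not tested.

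The chemokine receptor gene cxcr4b (ENSDARG00000041959, chromosome 9, 10721531 to 10723557), which guides migrating germ cells, fell from 214 to 80.3 FPKM (2.67-fold, q = 0.00107) in the authors' deposited table. It was the 1 lower gene among 8 called migration genes. The genes of its ligand, which somatic cells make, were higher in the authors' deposited table: cxcl12a by 11.8-fold (from 6.41 to 75.3 FPKM) and cxcl12b by 9.98-fold (from 15.15 to 151 FPKM). The adhesion repressor gene zeb1b was also higher there (from 8.13 to 42.4 FPKM). The split of the migration list did not pass the limit (adjusted p = 0.311, Fisher's exact test). Pluripotency and early zygotic factors were higher for 13 of 14 called members in the authors' deposited table, with klf2b the lower one, and the list missed the limit (adjusted p = 0.0722, Fisher's exact test). The Nodal co-receptor gene tdgf1 rose 12.1-fold (from 3.57 to 43.3 FPKM) and sox3 rose 7.52-fold (from 24.1 to 181 FPKM) in the authors' deposited table.

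The list with the largest median rise was that of muscle and paraxial mesoderm, the tissue that forms somites and skeletal muscle. Counted in the authors' deposited table, 25 of 26 called members were higher, with a median rise of 10.7-fold (adjusted p = 0.00293, Fisher's exact test). The somite polarity gene mespab (ENSDARG00000068761, chromosome 25, 10918620 to 10919879) rose from 1.18 to 72.3 FPKM (q = 0.00901) in the authors' deposited table. The presomitic mesoderm regulators msgn1 (from 32.8 to 751 FPKM, q = 0.00992) and tbx6 (from 28.6 to 597 FPKM, q = 0.00107) already had signal in the control samples in the authors' deposited table. The locus given there for msgn1 (chromosome 4, 149699 to 340476) is far longer than its coding sequence. The myogenic regulators myf5 (from 16.3 to 229.7 FPKM, 14.1-fold) and myod1 (from 6.38 to 68.1 FPKM, 10.7-fold) rose with them in the authors' deposited table. The exception was the slow troponin gene tnnt1, which the authors' deposited table gave at 1.67 FPKM in controls and listed at 0 in dead end morphants. Without members that another list also holds, 94.1% of this list was higher and the split no longer passed (adjusted p = 0.0710, Fisher's exact test).

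Neural genes rose without exception among those called: 46 of 46 in the authors' deposited table (adjusted p = 5.97e-08, Fisher's exact test), with a median rise of 4.34-fold. Among them, irx7 rose from 13.1 to 158 FPKM (q = 0.00107) and hoxb1b, a hindbrain patterning gene, rose 11.8-fold (from 23.9 to 283 FPKM) in the authors' deposited table. All 11 called neural crest genes were higher in the authors' deposited table (adjusted p = 0.0378, Fisher's exact test), led by twist1a (from 5.17 to 66.5 FPKM), snai1a (from 24.0 to 181 FPKM) and zic2a (from 8.74 to 59.5 FPKM). Without members that another list also holds, 5 neural crest genes were left and the split did not pass (adjusted p = 0.345, Fisher's exact test). The 12 called genes of epidermis and enveloping layer, the outer cell layers of the embryo, were likewise all higher in the authors' deposited table (adjusted p = 0.0252, Fisher's exact test). Their median rise was 2.87-fold, and cldni, a claudin gene, rose 7.41-fold (from 5.11 to 37.8 FPKM) in the authors' deposited table, with klf17 at 6.20-fold and tfap2a at 5.25-fold.

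Markers of other embryonic tissues had few called members, and each of these short lists stayed above the limit. Some of their members also stand in other lists. Without these, 3 of 8 endoderm, 2 of 5 heart and 5 of 8 pronephros genes were left. For notochord 4 of 7 and for hatching gland 2 of 7 were left, so the tissue results overlap. For blood and endothelium 4 of 43 listed genes were called, and for heart 5 of 19. Endoderm genes were higher for 8 of 8 in the authors' deposited table (adjusted p = 0.0763, Fisher's exact test), among them foxa2 (from 8.14 to 52.3 FPKM), foxa3 (from 10.1 to 60.8 FPKM) and hnf1ba (from 3.07 to 24.4 FPKM). The authors' deposited table listed sox32, the endoderm specifier, at 0 in controls and at 3.22 FPKM in dead end morphants. Blood and endothelial genes were higher for 4 of 4 there (adjusted p = 0.329, Fisher's exact test), including the vascular regulators etv2 (from 2.36 to 21.01 FPKM) and fli1a (from 1.103 to 14.4 FPKM) and the blood regulator tal1 (from 3.25 to 16.8 FPKM). Heart genes were higher for 5 of 5 (adjusted p = 0.201, Fisher's exact test), and the authors' deposited table gave hand2 at 3.08 and 14.9 FPKM, gata5 at 7.78 and 24.8 FPKM, and gata4 listed at 0 and at 2.04 FPKM. All 8 pronephros genes were higher in the authors' deposited table (adjusted p = 0.0763, Fisher's exact test), with irx3b up 11.2-fold and lhx1a up 6.83-fold. Notochord and axial mesoderm genes were higher for 7 of 7 (adjusted p = 0.126, Fisher's exact test), and in the authors' deposited table noto rose from 4.76 to 55.5 FPKM, shha from 2.55 to 25.3 FPKM and shhb from 0.636 to 18.3 FPKM. Hatching gland genes were higher for 7 of 7 (adjusted p = 0.126, Fisher's exact test), led in the authors' deposited table by gsc (from 2.81 to 35.7 FPKM), with prdm1a and klf17 also counted there. Of 4 called genes of the yolk syncytial layer and lipoproteins, 3 were higher (adjusted p = 1, Fisher's exact test), among them the apolipoprotein genes apoeb (from 407 to 1037 FPKM) and apoc1 (from 84.4 to 237 FPKM) in the authors' deposited table. With all 8 of 8 called members higher, Fisher's exact test gives p = 0.0572 before adjustment, so a list with up to 8 called members cannot pass by higher genes alone.

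**Figure D2:**
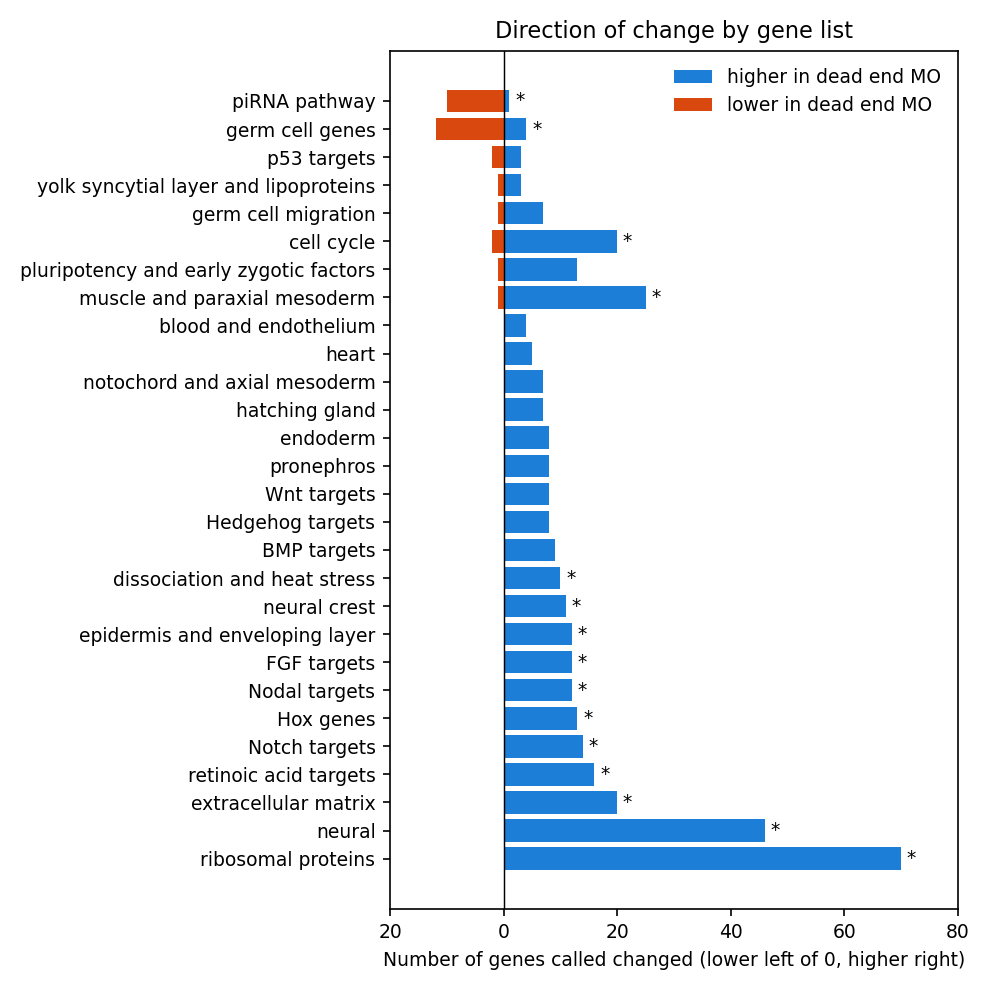
Number of genes called changed by the authors in each of 28 gene lists (1 bar per list), with lower genes drawn left of 0 in orange and higher genes right of 0 in blue; an asterisk marks an adjusted p under 0.05 by Fisher's exact test of the split against all other called genes. The germ cell and piRNA pathway lists have more lower genes (12 of 16 and 10 of 11), and 13 lists have more higher genes past the limit.

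Called members of the target lists of Notch, retinoic acid, FGF and Nodal signalling, which pattern the embryo, were all higher. These lists also hold ligand and receptor genes and members of other lists, so they do not measure the activity of a pathway. Without members that another list also holds, 7 Notch, 11 retinoic acid, 8 FGF and 5 Nodal genes were left. All 14 called Notch targets (adjusted p = 0.0128), all 16 retinoic acid targets (adjusted p = 0.00879), all 12 FGF targets (adjusted p = 0.0252) and all 12 Nodal targets (adjusted p = 0.0252) were higher in the authors' deposited table by Fisher's exact test. The segmentation clock genes her1 (from 13.0 to 272 FPKM) and her7 (from 14.1 to 153 FPKM) and the Delta ligand gene dld (from 16.9 to 207 FPKM) led the Notch list in the authors' deposited table. The retinoic acid degrading enzyme gene cyp26a1 rose 10.2-fold (from 21.6 to 220.1 FPKM) and the receptor gene raraa 7.03-fold (from 12.7 to 89.3 FPKM) in the authors' deposited table. In the FGF list, the ligand genes fgf17 and fgf8a rose 9.40-fold and 7.46-fold in the authors' deposited table. The Brachyury gene of the tailbud, ta, rose 7.05-fold there (from 28.3 to 199 FPKM). Lists for BMP (9 of 9 higher, adjusted p = 0.0569), Wnt (8 of 8, adjusted p = 0.0763) and Hedgehog targets (8 of 8, adjusted p = 0.0763) missed the limit of Fisher's exact test. In the authors' deposited table the BMP targets vox (from 32.9 to 233 FPKM), tp63 (from 7.46 to 39.9 FPKM) and msx1b (from 13.2 to 61.3 FPKM) and the Wnt targets ccnd1 (from 56.8 to 713 FPKM) and sp5l (from 48.4 to 348 FPKM) were higher. Hox genes, which set position along the body axis, were higher for all 13 called members (adjusted p = 0.0195, Fisher's exact test), by 3.36-fold to 17.9-fold in the authors' deposited table. The largest of these were hoxc3a (from 19.6 to 349.7 FPKM), hoxb1b and hoxb3a (from 6.54 to 76.3 FPKM) in the authors' deposited table. At q under 0.01 the called members of the Notch, retinoic acid, FGF, Nodal, Hox, neural crest and epidermis lists were again all higher, and these lists no longer passed the test. Without members that another list also holds, the neural, extracellular matrix and ribosomal protein lists were the 3 that passed with more higher genes.

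Ribosomal protein genes formed the largest list, with 70 of 70 called members higher in the authors' deposited table (adjusted p = 6.12e-12, Fisher's exact test). The rises of these called members were mostly small, with a median of 2.35-fold and a 5th to 95th percentile range of 1.95-fold to 3.08-fold. The smallest absolute log2 change of any gene with q under 0.05 was 0.829. No smaller rise entered, so the narrow range partly reflects how genes were called. The gene rps20 stood apart in the authors' deposited table with a rise of 7.48-fold (from 408 to 3054 FPKM), ahead of rps26 (3.40-fold) and rpl37 (3.34-fold). The median rise of the list lay at percentile 5.76 of 10000 random lists of called genes matched on expression.

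Extracellular matrix genes were higher for all 20 called members in the authors' deposited table (adjusted p = 0.00293, Fisher's exact test), among them the hyaluronan synthase gene has2 (from 2.60 to 27.6 FPKM), efemp2b (from 23.8 to 198 FPKM) and the fibronectin gene fn1b (from 36.6 to 232 FPKM). Cell cycle genes were higher for 20 of 22 (adjusted p = 0.0252, Fisher's exact test), with ccnd1, the cyclin D1 gene, up 12.6-fold and ccne2 up 5.90-fold in the authors' deposited table. The exceptions in the authors' deposited table were wee2, an oocyte kinase gene that restrains meiosis (from 55.5 to 12.4 FPKM), and ccna2 (from 359 to 131 FPKM). Genes of dissociation and heat stress, which cell sorting can induce, were higher for all 10 called members in the authors' deposited table (adjusted p = 0.0378, Fisher's exact test). They included the collagen chaperone gene serpinh1b (from 85.8 to 559 FPKM), hsp90aa1.1 (from 18.2 to 109 FPKM) and hspb1 (from 812 to 3345 FPKM) in the authors' deposited table, and hsp90aa1.1 is also a muscle chaperone gene. The stress call ended with a minimum of 5 FPKM, and the stress and cell cycle calls ended at q under 0.01 and without members of other lists. The p53 targets were split, 3 higher and 2 lower (adjusted p = 1, Fisher's exact test): btg2 (from 90.9 to 341 FPKM) and baxa (from 12.3 to 43.5 FPKM) rose and sesn2 fell (from 46.9 to 12.8 FPKM) in the authors' deposited table.

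Among single genes, the largest rises in the authors' deposited table were in mespab, msgn1, admp, tbx6, her1, her11, hoxc3a and pou5f3, ranked by log2 of FPKM plus 1. The BMP-like organizer gene admp rose from 0.712 to 33.9 FPKM (47.6-fold, q = 0.00722) and the segmentation clock gene her11 from 3.98 to 86.6 FPKM (21.8-fold, q = 0.00381) in the authors' deposited table. The largest falls included slc16a3, a lactate transporter gene, which fell from 285 to 23.1 FPKM (12.4-fold, q = 0.00107) in the authors' deposited table. The maternal TGF-beta ligand gene gdf3 fell 10.2-fold (from 195 to 19.0 FPKM) and tnfaip8l1 11.6-fold (from 57.3 to 4.95 FPKM) in the authors' deposited table. Lower values also stood there for kpna7, an importin gene (from 16.0 to 0.608 FPKM), for fdft1, the squalene synthase gene (from 25.8 to 1.73 FPKM), and for cfap74, a cilium gene (from 10.6 to 0.178 FPKM). The authors' deposited table listed otud4, a deubiquitinase gene, at 419 FPKM in controls and at 0 in dead end morphants, over a locus of 168 bp (chromosome 5, 822114 to 822282), and marveld3, a tight junction gene, at 16.2 FPKM and at 0.

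The authors' own enrichment tables described the same comparison by Gene Ontology term, with higher and lower genes each set against all zebrafish genes. Higher genes were enriched for 374 terms. In the authors' deposited table these included embryo development (197 genes, 4.80-fold, p = 7.29e-70), nervous system development (192 genes, 3.22-fold, p = 3.87e-42) and translation (85 genes, 6.27-fold, p = 3.28e-36). Terms for single tissues in the authors' deposited table included hindbrain development (42 genes, 8.70-fold, p = 5.93e-22), somitogenesis (38 genes, 8.50-fold, p = 2.58e-19) and heart development (63 genes, 3.52-fold, p = 1.31e-13). Endoderm development (18 genes, 8.65-fold, p = 3.34e-08) and pronephros development (26 genes, 5.65-fold, p = 1.37e-08) were also enriched in the authors' deposited table. Lower genes were enriched for 21 terms, 8 of them at p under 0.001. In the authors' deposited table these were led by metabolic process (181 genes, 1.57-fold, p = 6.29e-08), a term also enriched among higher genes (431 genes, 1.55-fold, p = 6.89e-20), and catabolic process had 40 genes (2.63-fold, p = 0.000148). Oogenesis had 7 lower genes (10.33-fold, p = 0.0219 with Bonferroni correction) in the authors' deposited table, and the cellular response to DNA damage had 18 (3.35-fold, p = 0.0371). The background of these tests was the whole genome rather than the genes expressed in germ cells, so a term can be enriched because germ cells express its genes at all.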

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

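Of 140 combinations of a list and a setting, 116 kept their side of the threshold, 23 lost it, 1 gained it and 0 reversed. The gain was that of the pluripotency factors without a minimum FPKM. The settings changed only which genes entered, not their directions, and 20 lists had no lower member. Most combinations could therefore hardly have reversed, and the lack of reversals says little about stability. At q under 0.01, the authors' deposited table gave 1047 higher and 416 lower genes, and 4 lists passed with more higher genes, against 13. Without members that another list also holds, 3 lists passed with more higher genes and 0 with more lower genes, against 13 and 2. Fewer genes enter those tests. The dissociation stress list also lost its call with a minimum of 5 FPKM and with genes listed at 0 left out, an alternative chosen after seeing the data. Its 10 called members were the same in number and all higher in both settings. The share of higher genes among all other called genes went from 65.6% to 68.2% and 68.1%, so the comparison genes moved and not the list. At p under 0.001 the authors' deposited table of lower genes had 8 terms, against 21, as the stricter limit implies. Pseudocounts of 0.1 and 5 reversed 0 of 232 directions of change, over lists, named genes and the medians of higher and lower genes. A pseudocount cannot change which group has the higher value, and the medians follow the majority of their genes. This count was therefore fixed in advance and checks nothing.

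No paired analysis was possible because the table used here gives 1 value per group, although the labels number the libraries of both groups 1 and 2. For the same reason the leaving out of libraries, a rescaling to the median gene, count models and a list test with an estimated correlation were not run. Depth is unknown, so it cannot be said which low values are limited by it.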

Other observations

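All added gene lists and tests in this part were chosen after the results were seen, so the p-values of these lists restate what prompted them and are not independent evidence. Among genes of mitochondrial and peroxisomal fatty acid oxidation, all 6 called members were lower in the authors' deposited table (adjusted p = 0.0177, Fisher's exact test, adjusted over 14 added lists). The acyl-CoA dehydrogenase genes acadm (from 93.1 to 15.4 FPKM) and acadl (from 19.8 to 1.88 FPKM) fell 6.03-fold and 10.5-fold in the authors' deposited table, and the peroxisomal gene ehhadh fell from 19.99 to 2.71 FPKM. Solute carrier genes leaned lower, 18 of 29 in the authors' deposited table (adjusted p = 0.0177, Fisher's exact test), led by slc16a3. The egg coat genes of the zona pellucida family were lower for all 4 called members, among them zp3b (from 31.1 to 7.19 FPKM) and zp3c (from 23.8 to 3.21 FPKM) in the authors' deposited table, without passing the limit (adjusted p = 0.0637, Fisher's exact test). Lysosomal genes were lower for 7 of 10 (adjusted p = 0.0879), endoplasmic reticulum folding genes for 4 of 6 (adjusted p = 0.241) and mitochondrial ribosome genes for 2 of 3 (adjusted p = 0.316), by Fisher's exact test in the authors' deposited table.

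Nucleolar and splicing factors were higher but did not pass. All 9 called nucleolar factors were higher in the authors' deposited table (adjusted p = 0.0879, Fisher's exact test), among them the fibrillarin gene fbl (from 131 to 369 FPKM) and the nucleophosmin gene npm1a (from 214 to 604 FPKM). All 9 SR and hnRNP splicing factors were higher in the authors' deposited table (adjusted p = 0.0879, Fisher's exact test), led by srsf7a (from 73.1 to 355 FPKM). Translation initiation and elongation factors were higher for 15 of 17 (adjusted p = 0.139, Fisher's exact test). Families of developmental regulators leaned higher in the authors' deposited table without passing Fisher's exact test: sox genes for 9 of 10 (adjusted p = 0.241), frizzled receptors for 6 of 6 (adjusted p = 0.176), iroquois genes for 5 of 5 (adjusted p = 0.241) and zic genes for 4 of 4 (adjusted p = 0.329). Rab GTPase genes were split, 7 higher and 6 lower (adjusted p = 0.387, Fisher's exact test). Listed at 0 in the authors' deposited table were 156 lower genes with the dead end morpholino (17.97% of the 868 lower genes before the FPKM minimum) and 76 higher genes with the control (4.72% of 1609 higher genes), most of them low in the other group as well (medians of 1.55 and 2.03 FPKM).

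The fall of germ cell transcripts may come from each gene or from a smaller share of germ cell RNA in the dead end samples, as other cells in the sort would give, which would lower every germ cell transcript by a common factor. The 12 lower germ cell genes had a weighted mean change of -1.94 on the log2 scale (SE 0.20), with single values from -1.12 to -3.56. Cochran's Q test of the spread of these values gave p = 0.324 (n = 12 genes). That test used standard errors implied by the authors' statistic, 0.48 to 0.94, under the assumption that the statistic is the log ratio over its standard error, and it left out the 4 members that rose and all members not called. As the change itself chose its genes, the test decides nothing. Dilution and a loss of each transcript with the dead end morpholino cannot be told apart without values per library.

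The rise of somatic genes could come from embryo cells caught in the sort, and if these had the make-up of the whole embryo and germ cells lacked the markers, all tissues should have risen alike. Over all called genes held by 1 of the 11 tissue lists only (112 genes, those listed at 0 included), the authors' log2 changes differed between tissues, with medians of 3.42 for muscle and paraxial mesoderm, 2.11 for neural and 1.47 for epidermis genes (Kruskal-Wallis statistic, permutation p = 2.0e-05, 100000 permutations within 3 bins of mean FPKM). Without the muscle list the permutation p was 0.00446 over 87 genes, so the called genes did not rise alike across tissues. The change itself chose these genes, they are not independent units, and germ cells may not lack the markers. The test therefore does not decide whether embryo cells were caught in the sort. The abundant keratin gene krt8 went from 198 to 358 FPKM and the muscle actin gene actc1a from 25.9 to 168 FPKM in the authors' deposited table. Embryo cells in the gate, of all or of selected tissues, stay open as a cause. So do a baseline of some markers in germ cells and somatic genes switched on in germ cells of dead end morphants. How many cells of other types passed the gate on germline EGFP was not measured here.

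The rise of all called ribosomal protein genes may reflect a shift in scaling, under which other genes of like abundance should also be higher. Of 83 other called genes in the same range of mean FPKM, 91.6% were also higher (Fisher's exact test against the 62 ribosomal protein genes in that range, p = 0.0201). Among 57 other genes that also matched in locus span, 94.7% were higher (p = 0.243, Fisher's exact test against 56 ribosomal protein genes). A scaling shift, a gain of signal over short loci and a rise of ribosomal protein transcripts cannot be told apart, because genes that did not change were not analysed here. A different make-up of the sorted cells and an effect of the dead end morpholino on the germ cells also stay open. Neither was tested for these genes.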
